A study of Homo sapiens with 58 samples.

How the data were processed

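Total RNA, labelled with biotin, was measured on 58 gene expression arrays of human CD8+ T cells that had been sorted by surface TIGIT, an inhibitory receptor of T cells and natural killer (NK) cells. The cells came from 29 donors: 15 negative, 8 aviremic and 6 viremic, and each donor gave 1 TIGIT+ and 1 TIGIT- array. The status was read from the letter in each sample title together with the group sizes given for the series, and the number in the title paired the 2 fractions of a donor. The virus itself is not named in the sources used here.

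The deposited table held 49624 probes with log2 values, as the authors deposited them, and had no missing value. Base 2 was inferred from the values, whose highest per array lay between 12.5 and 13.1. The submitters' processing notes name limma, without a version or a role, and the normalization and the summary of probes are not given in the sources used here. The medians of the arrays lay between 2.78 and 2.94, so the deposited values were used without further scaling. Arrays give no counts, and their number limits the precision of every value.

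The platform table listed a gene for 25650 probes, of which 23808 had a single symbol, 1842 had several and the other 23974 probes had none. Of the single-symbol probes, 22511 matched the human reference gene table (GRCh38.p14) by Entrez identifier, and all of these carried the same symbol there. That table served for names only, since the platform's genome build is not given, and no coordinates are printed. The 42 probes of Y-linked genes, XIST and TSIX were left out before any test. Of the 23766 probes kept, 14920 had a mean over all arrays above 2.83, the median of the means of all probes. Each gene was represented by its probe with the highest mean, which left 13958 genes. Probes with several symbols or none were not used in the comparisons.

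All comparisons were made with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and the R package data.table, version 1.17.8, was used to read the values. TIGIT+ was compared with TIGIT- cells with the donor as a fixed block, over all donors and within each status in a joint fit, and contrasts of that fit tested whether the TIGIT effect differed between statuses. Donor status was compared within each fraction over 29 arrays, with all 3 statuses in the same fit. P values are two-sided and were adjusted by Benjamini and Hochberg over the 13958 genes, with a threshold of 0.05 on the adjusted p. Differences are on the log2 scale with the standard error (SE) of the fit, and spreads of levels are standard deviations (SD) over donors. "Rose" and "fell" are used only of genes past the threshold, and counts of a list's members are given over all genes and, where stated, adjusted over the list alone.

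The 21 gene lists were written from textbook knowledge before the data were examined, as were the comparisons, tests, thresholds, all alternatives but 2, and the rule for naming genes. Lists were tested with limma's camera at its preset correlation between genes of 0.01 and, beside it, with an estimated correlation, adjusted over the lists of a comparison; fry, which tests whether a list's genes move to one side on balance without comparing them with other genes, was an alternative. Of the listed genes, 43 had no probe with a single symbol, among them PDCD1 and TCF7. Genes were named as follows. TIGIT came first. Over all donors the 10 largest rises and 10 largest falls with the same sign in at least 26 of 29 donors were taken, with up to 4 members of each list by smallest p and its brightest member not past the threshold. The same genes were followed within each status. For a status comparison up to 8 rises and 8 falls were taken, with up to 4 members of each list that passed camera, and for a comparison without a gene past the threshold the 3 with the smallest p. HLA-DR and HLA-DQ chains, KIR genes and other genes with common inherited absence were not named in status comparisons.

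The pairing of the fractions was checked. After removal of group means, the 2 arrays of a donor correlated with a median r of 0.34 across probes, against -0.012 for arrays of different donors, and in 25 of 29 donors the TIGIT+ array correlated best with the donor's own TIGIT- array. Correlations across probes treat probes as replicates, which they are not. No 2 arrays were identical. Arrays whose SD, mean or 5th percentile over all probes lay over 4 median absolute deviations from the median of the arrays were treated as doubted; there were 2, both of TIGIT+ cells, and the TIGIT- arrays of the same donors were not doubted.

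The fits were tested on simulated data with known changes in the same design. At 2-fold, all of 50 changed genes were recovered in the comparison of fractions over all donors, 96% within the viremic donors, 90% for the difference of the TIGIT effect between viremic and negative donors, and 98% for viremic against negative donors in either fraction. At 1.25-fold the recovery was 92% over all donors and 22% for viremic against negative donors. Between 2.90% and 6.71% of the calls in the simulated data were unchanged genes. Each gene was simulated independently of the others, so the effect of correlation between genes on these shares was not tested.

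The alternatives were centring each array on its median, quantile normalization, no filter on dim probes, only probes above the 75th percentile of the means, the mean of a gene's probes, a trend with a robust prior, array weights, no replicate block, the block as a random effect, and leaving out each donor in turn. Leaving out the donors with a doubted array and a covariate for each array's 5th percentile were added after seeing the data. Other splits of the samples were drawn 100 times, or enumerated where fewer exist. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.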

Results

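Gene expression was measured in CD8+ T cells of 29 donors, sorted into a TIGIT+ and a TIGIT- fraction, on 58 arrays. The donors were 15 negative, 8 aviremic and 6 viremic, and each gave both fractions. After the filters 13958 genes were tested. The number of arrays per group limits the precision of what follows. The series asks how the expression programme of TIGIT-bearing CD8+ T cells relates to their killing capacity; donor status adds the question of whether that programme changes with viremia.

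TIGIT itself followed the sort in every donor. Over all donors its signal (probe 16944199) was 4.16-fold higher in the TIGIT+ fraction (log2 difference 2.06, SE 0.08, adjusted p = 8.56e-20), with paired differences between 1.28 and 2.92 in 29 of 29 donors. The TIGIT+ level was 5.29 ± 0.38 (SD, n = 15) in negative, 5.37 ± 0.27 (SD, n = 8) in aviremic and 5.58 ± 0.35 (SD, n = 6) in viremic donors. The TIGIT- level was 3.17 ± 0.57 (SD, n = 15) in negative, 3.09 ± 0.40 (SD, n = 8) in aviremic and 3.98 ± 0.34 (SD, n = 6) in viremic donors.

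**Figure D1:**
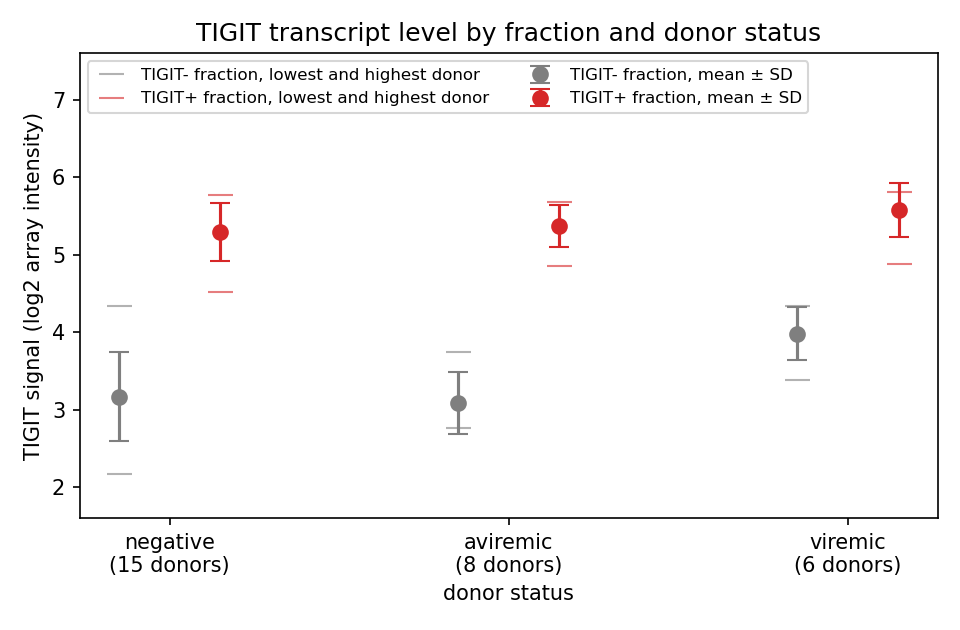
TIGIT signal (log2 array intensity, vertical axis) in the TIGIT- and TIGIT+ fractions of negative, aviremic and viremic donors (horizontal axis); points and bars are mean ± SD over donors, short lines the lowest and highest donor. The TIGIT+ means lie between 5.29 and 5.58 and the TIGIT- means between 3.09 and 3.98.

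TIGIT+ and TIGIT- CD8+ T cells were compared over all donors to find what distinguishes the fractions. TIGIT+ cells had far less of the transcripts of naive and resting memory cells and more of those of cytotoxic, activated and dividing cells. The cytotoxic, activation and cell cycle lists passed camera with the preset correlation alone (adjusted p = 0.153, 0.0833 and 0.114 with an estimated correlation). The neuronal-type leucine-rich repeat gene LRRN3, a marker of naive T cells, was 7.40-fold lower (log2 -2.89, SE 0.14) and MAL, a membrane raft protein, 5.11-fold lower (-2.35, SE 0.14). LEF1, a transcription factor of naive T cells, was 3.40-fold lower (-1.77, SE 0.11). Each was lower in 29 of 29 donors. GZMK, which encodes granzyme K, was 3.43-fold higher (1.78, SE 0.13), and the Fc receptor-like gene FCRL3 4.78-fold higher (2.26, SE 0.12), in 29 of 29 donors. In limma 6281 of 13958 genes passed the threshold, of which 3094 rose and 3187 fell, and 130 rises and 80 falls exceeded 2-fold. The difference had a single sign in at least 26 donors for 1910 of these genes.

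The largest falls with a single sign in nearly all donors, after LRRN3, were CHRM3-AS2 (-2.88, SE 0.11), MAL, the desmosomal cadherin gene DSC1 (-2.11, SE 0.13), SCML1 (-2.05, SE 0.12), the protein kinase C gene PRKCA (-1.94, SE 0.10), the Tec-family kinase gene TXK (-1.91, SE 0.11), SNORA47 (-1.80, SE 0.12), ACTN1 (-1.78, SE 0.08) and LEF1. Among the naive and central memory genes 17 of 19 measured members fell and none rose (median log2 difference -1.56). This was the only list of the 21 that passed camera with an estimated correlation as well (adjusted p = 0.0468 with an estimated correlation). BACH2, a repressor that holds T cells in a resting state, fell by 1.66 (SE 0.08) and SERINC5 by 1.56 (SE 0.08), each in 29 of 29 donors. CD27, a costimulatory receptor kept by memory cells, had a log2 difference of 0.07 (SE 0.05, adjusted p = 0.305).

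Of 13 cytotoxic granule genes 11 rose, none fell and 2 were not past the threshold (median log2 difference 0.66); adjusted over the list alone 12 rose. After GZMK, GZMA rose by 1.30 (SE 0.13), GZMM by 0.69 (SE 0.06) and SRGN, the granule proteoglycan serglycin, by 0.57 (SE 0.06), all in 29 of 29 donors. GNLY, which encodes granulysin, had a log2 difference of 0.05 (SE 0.18, adjusted p = 0.844). The list passed camera with the preset correlation (adjusted p = 7.29e-07) and not otherwise (adjusted p = 0.153 with an estimated correlation). Of 8 measured effector cytokines and chemokines 5 rose and 2 fell, and the list did not pass camera (adjusted p = 0.0880). IFNG rose by 1.56 (SE 0.16), CCL4 by 1.41 (SE 0.16) and CCL5 by 0.64 (SE 0.08). LTB, the lymphotoxin beta gene of resting lymphocytes, fell by 0.84 (SE 0.09). TNF had a log2 difference of 0.19 (SE 0.11, adjusted p = 0.172).

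Inhibitory receptors other than TIGIT rose in 7 of 11 cases and fell in 3 (median 0.52; adjusted p = 0.114 with an estimated correlation). CD160 was 4.42-fold higher (2.14, SE 0.12), CTLA4 2.16-fold (1.11, SE 0.14) and CD244 2.10-fold (1.07, SE 0.10). LAG3 rose by 0.52 (SE 0.05). CD200R1 had a log2 difference of -0.11 (SE 0.09, adjusted p = 0.318). Of 17 effector transcription factors 12 rose and 1 fell (median 0.47; adjusted p = 0.114 with an estimated correlation), led by EOMES (1.64, SE 0.11), a T-box factor of effector and exhausted cells, TOX (1.49, SE 0.13), a factor of chronically stimulated cells, and IRF4 (1.0, SE 0.10). BATF rose by 0.50 (SE 0.06). BHLHE40 had a log2 difference of -0.14 (SE 0.10, adjusted p = 0.256). Homing receptors rose in 11 of 18 cases and fell in 2 (median 0.22; adjusted p = 0.231 with an estimated correlation). CXCR5, which guides lymphocytes to B cell follicles, was 3.32-fold higher (1.73, SE 0.11) and CXCR3 2.19-fold higher (1.13, SE 0.10).

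Of 15 activation markers 11 rose and 1 fell (median 0.73; adjusted p = 0.0833 with an estimated correlation). TNFRSF9, the costimulatory receptor 4-1BB, was 3.94-fold higher (1.98, SE 0.10), HLA-DMA 2.41-fold (1.27, SE 0.08), CIITA, the class II transactivator, 2.33-fold (1.22, SE 0.09) and HLA-DRA 5.37-fold (2.43, SE 0.18). CD69 had a log2 difference of 0.05 (SE 0.05, adjusted p = 0.370). Of 17 cell cycle genes 16 rose and none fell (median 0.38; adjusted p = 0.114 with an estimated correlation). The spindle gene NUSAP1 rose by 1.04 (SE 0.09), the topoisomerase gene TOP2A by 1.04 (SE 0.11), the mitotic kinesin gene KIF11 by 0.93 (SE 0.09) and MKI67 by 0.74 (SE 0.10). Of 20 interferon-stimulated genes 10 rose and 1 fell, and 3 fell when adjusted over the list alone (median 0.11; adjusted p = 0.231 with an estimated correlation). OAS1 rose by 0.63 (SE 0.06) and ISG15 by 0.35 (SE 0.05). Immediate early genes rose in 7 of 13 cases and fell in 2 (adjusted p = 0.333 with an estimated correlation), with a rise of DUSP2 by 0.85 (SE 0.06) and a fall of FOS (-0.46, SE 0.08).

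Transcripts typical of other cell types were also higher in the TIGIT+ fraction and so moved with the cytotoxic, activation and NK-type genes. Immunoglobulin variable genes gave the largest rises of all: IGKV1-5 was 8.47-fold higher (3.08, SE 0.25), IGKV2-24 7.76-fold (2.96, SE 0.28), IGLV1-40 6.39-fold (2.68, SE 0.29) and IGHV1-18 5.80-fold (2.54, SE 0.21). IGKV1D-39, IGKV1-6 and IGHV3-15 rose by between 2.28 and 2.41. Of 6 B cell markers 4 rose and none fell (adjusted p = 0.114 with an estimated correlation), among them IGHM (2.20, SE 0.17) and MS4A1, which encodes CD20 (1.90, SE 0.09). CD79A stood at 6.68 in TIGIT+ and 6.92 in TIGIT- cells (adjusted p = 0.331). All 7 monocyte and dendritic cell markers rose (adjusted p = 0.189 with an estimated correlation), with LYZ, the lysozyme gene, 5.71-fold higher (2.51, SE 0.26). Of 5 platelet and erythroid markers 3 rose (adjusted p = 0.230 with an estimated correlation), with the platelet chemokine gene PPBP 3.31-fold higher (1.73, SE 0.24). These lists passed camera with the preset correlation.

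NK-type receptors and adaptors rose in 9 of 13 cases and fell in 2 (median 0.49; adjusted p = 0.231 with an estimated correlation). NK cell markers, which share 5 genes with them, rose in 6 of 7 cases (adjusted p = 0.114 with an estimated correlation). The receptor gene KLRF1 was 3.64-fold higher (1.87, SE 0.19), the signalling adaptor gene TYROBP 3.16-fold (1.66, SE 0.16) and NCR1 2.17-fold (1.12, SE 0.10). FCER1G had a log2 difference of -0.39 (SE 0.18, adjusted p = 0.0839). Of 7 gamma-delta and MAIT cell markers 5 fell, among them ZBTB16 (-0.64, SE 0.11) and CCR6 (-0.55, SE 0.11), and 1 rose, TRDC, the constant region of the T cell receptor delta chain, by 2.16 (SE 0.24). The list did not pass camera (adjusted p = 0.0610). CD4 and regulatory T cell markers rose in 3 of 6 cases and fell in 2 (adjusted p = 0.364). CCR4 rose by 0.89 (SE 0.19) and IL2RA fell by 0.52 (SE 0.11). FOXP3 had a log2 difference of -0.01 (SE 0.06, adjusted p = 0.892).

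Housekeeping lists were read as well, and apart from the ribosomal protein genes their members passed in both directions. Ribosomal protein genes fell in 7 of 9 cases (median -0.17; adjusted p = 0.114 with an estimated correlation), with RPL32 at -0.41 (SE 0.07). Oxidative phosphorylation genes rose in 3 and fell in 4 of 15 cases (adjusted p = 0.954), glycolysis genes rose in 8 and fell in 3 of 16 (adjusted p = 0.402), and heat shock genes rose in 3 and fell in 2 of 5 (median 0.12, mean -0.0059, adjusted p = 0.780). Among these, GAPDH rose by 0.34 (SE 0.05), HK2, the first enzyme of glycolysis, fell by 0.50 (SE 0.07), and BAG3, a cochaperone, fell by 0.48 (SE 0.04).

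**Figure D2:**
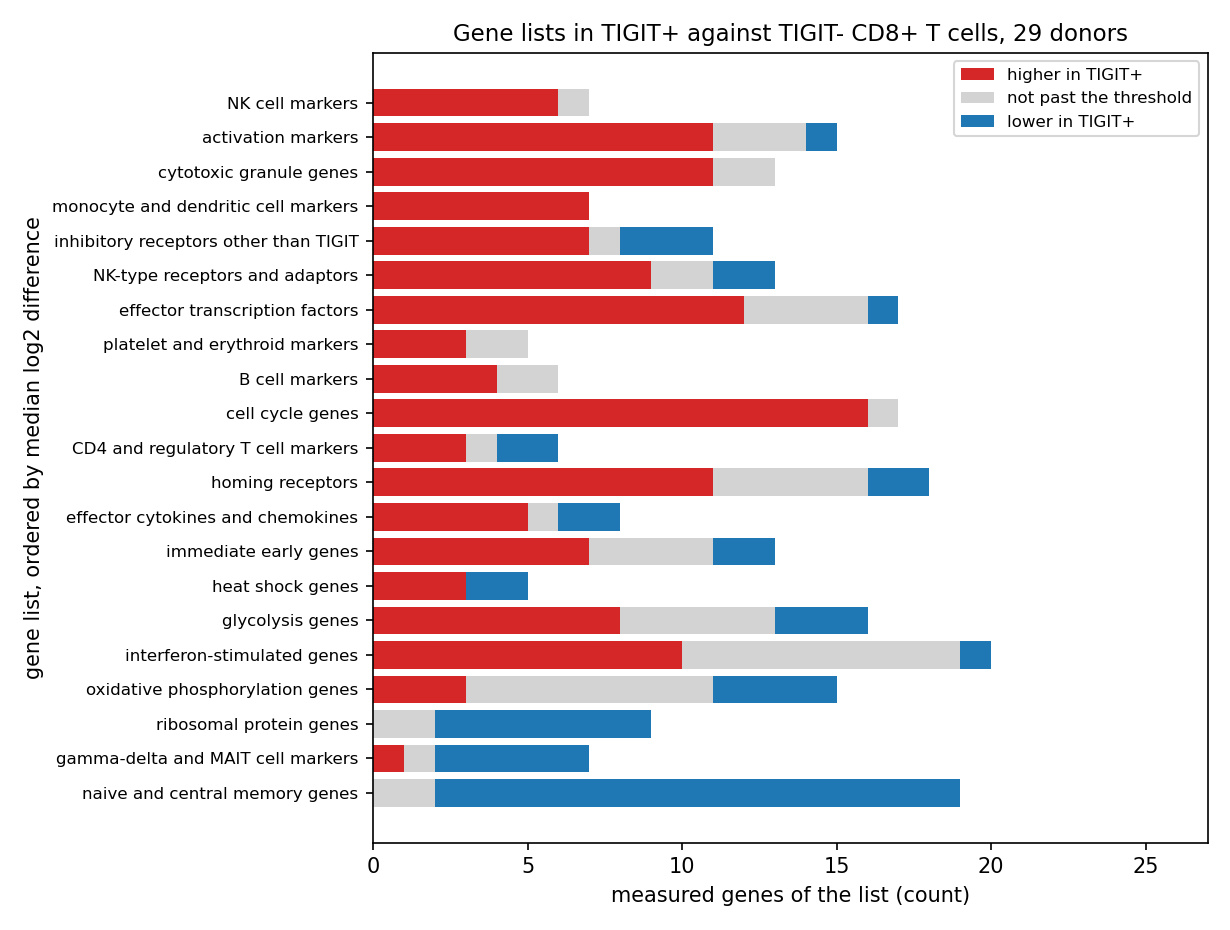
Measured members of each gene list (horizontal axis, count of genes) that were higher, lower or not past the threshold in TIGIT+ against TIGIT- CD8+ T cells over 29 donors, with lists (vertical axis) ordered by their median log2 difference. Naive and central memory genes show 17 of 19 members lower and cell cycle genes 16 of 17 higher.

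The same contrast was read within each status to see whether the difference between fractions was present in each group of donors. Each array measures a fraction as a whole, and the mix of cells within it was not measured. In 15 negative donors 4724 genes passed the threshold (2145 rose and 2579 fell), in 8 aviremic donors 3163 (1798 rose and 1365 fell) and in 6 viremic donors 1442 (633 rose and 809 fell). LRRN3 was 6.74-fold lower in negative (-2.75, SE 0.19), 7.11-fold lower in aviremic (-2.83, SE 0.26) and 9.83-fold lower in viremic donors (-3.30, SE 0.30). GZMK was 3.57-fold higher in negative (1.84, SE 0.18), 3.83-fold in aviremic (1.94, SE 0.24) and 2.69-fold in viremic donors (1.43, SE 0.28). CD160 was 4.40-fold, 5.01-fold and 3.78-fold higher. Negative and aviremic donors shared 1454 rises where 276 would be shared by chance and 1238 falls where 252 would be. Negative and viremic donors shared 530 rises (97.3 by chance) and 710 falls (149 by chance). Aviremic and viremic donors shared 476 rises (81.5 by chance) and 561 falls (79.1 by chance). The numbers by chance assume independent calls. The statuses share each gene's spread in the joint fit, so these numbers may be too low and were not used as a test. A single gene went opposite ways between negative and aviremic donors, a single gene between negative and viremic donors, and 0 between aviremic and viremic donors.

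Naive and central memory genes fell in 17 of 19 cases in negative, 16 in aviremic and 16 in viremic donors, and passed camera with either correlation in all 3 statuses (adjusted p = 0.0292, 0.0216 and 0.00512 with an estimated correlation). Counts of members are not alike between statuses, as fewer donors give fewer calls. In simulated data 96%, 86% and 66% of 1.5-fold changes were recovered in negative, aviremic and viremic donors. Cytotoxic granule genes rose in 12 of 13 cases in negative, 9 in aviremic and 3 in viremic donors, where the list did not pass camera (adjusted p = 0.0698). In negative and aviremic donors it passed with the preset correlation alone (adjusted p = 0.0894 and 0.114 with an estimated correlation). In viremic donors GZMA had a log2 difference of 0.58 (SE 0.26, adjusted p = 0.160) and GNLY of -0.87 (SE 0.35, adjusted p = 0.122), and GZMM rose by 0.70 (SE 0.13). Effector transcription factors rose in 12, 11 and 3 of 17 cases in negative, aviremic and viremic donors and fell in 1, 0 and 2. The list lost its call in negative and aviremic donors (adjusted p = 0.0687 and 0.0727 with an estimated correlation) and did not pass camera in viremic donors (adjusted p = 0.159). Cell cycle genes rose in 11, 14 and 4 of 17 cases, and the list kept its call in aviremic donors (adjusted p = 0.0353 with an estimated correlation) but not in negative and viremic donors (adjusted p = 0.0699 and 0.428 with an estimated correlation). Activation markers rose in 11, 10 and 9 of 15 cases. With an estimated correlation they passed in negative and aviremic donors (adjusted p = 0.0292 and 0.0216) and not in viremic donors (adjusted p = 0.155 with an estimated correlation). B cell markers rose in 4, 2 and 3 of 6 cases. In viremic donors they were, beside the naive genes, the only list of the 21 to pass with an estimated correlation (adjusted p = 0.0112), and MS4A1 was 3.74-fold, 4.24-fold and 3.19-fold higher. The count in viremic donors fell to 831 genes without viremic replicate 5. Without the pairing of fractions by donor it was 564, and that in aviremic donors 2026.

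Whether the TIGIT effect differed between statuses was tested directly, and no single gene passed. In limma 0 genes differed across the 3 statuses, with 775 at an unadjusted p under 0.05. For viremic against negative donors 0 passed (896 unadjusted), for aviremic against negative donors 0 (476 unadjusted) and for viremic against aviremic donors 0 (1039 unadjusted). The smallest p values belonged to TOX, whose TIGIT effect was smaller in viremic than in aviremic donors (difference -1.47, SE 0.29, adjusted p = 0.137), the G protein-coupled receptor kinase gene GRK5 (-0.68, SE 0.13, adjusted p = 0.137) and APOBEC3D (-0.57, SE 0.12, adjusted p = 0.206). GRK5, TOX and SPOCK2 also led the test across statuses (adjusted p = 0.399). Between viremic and negative donors they were CACNA1C-AS1 (-0.60, SE 0.13), PEG10 (0.65, SE 0.14) and SPOCK2 (-0.50, SE 0.11; adjusted p = 0.293 for each). Between aviremic and negative donors they were KIF9-AS1 (0.43, SE 0.10), TBC1D29P (-0.67, SE 0.17) and TSKS (0.37, SE 0.09; adjusted p = 0.998 for each). GRK5 passed after quantile normalization (adjusted p = 0.0374), GRK5 and TOX with array weights (adjusted p = 0.0417), and SPOCK2 without viremic replicate 1 (adjusted p = 0.0206 for viremic against negative donors).

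At the level of lists the TIGIT effect mostly had a lower signed value in viremic than in negative donors. With the preset correlation 14 of 21 lists differed, 13 of them towards a lower value in viremic donors, and 4 of the 14 also passed with an estimated correlation. With fry none of the 21 passed (adjusted p = 0.0622 for each of the 4). A lower value was not always a smaller difference between fractions: naive and central memory genes, 1 of the 13, went from a mean of -1.23 in negative to -1.42 in viremic donors (adjusted p = 0.363 with an estimated correlation). The 4 lists were the effector transcription factors (median log2 difference 0.47 in negative and 0.15 in viremic donors; adjusted p = 0.0445 with an estimated correlation), the effector cytokines and chemokines (0.30 and 0.18; adjusted p = 0.0445), the homing receptors (0.26 and 0.02; adjusted p = 0.0445) and the CD4 and regulatory T cell markers (0.30 and 0.05; adjusted p = 0.0451). For the cytokines in viremic donors camera gave a downward direction beside the positive median and a mean of 0.04. Cytotoxic granule genes differed in the same direction (adjusted p = 0.120 with an estimated correlation). Between viremic and aviremic donors 14 lists passed with the preset correlation and 0 with an estimated correlation. With fry 3 passed, the effector transcription factors, the homing receptors (adjusted p = 0.0367 for each) and the activation markers (adjusted p = 0.0374).

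TIGIT+ cells of viremic donors were compared with those of negative and aviremic donors to ask what differs with viremia within the fraction. Status was compared across different donors, and no age, sex, treatment or array run entered these fits. Other differences between the donors may therefore contribute to every status comparison. They had more IFNG, which encodes interferon gamma, and fewer naive-type transcripts. Against negative donors IFNG was 3.24-fold higher (1.70, SE 0.29) and the cytoskeletal adaptor gene PDLIM1 2.58-fold higher (1.37, SE 0.21; n = 6 and 15). KLRB1, the receptor CD161 of MAIT and related cells, was 3.49-fold lower (-1.80, SE 0.34) and DPP4, which encodes CD26, 2.37-fold lower (-1.25, SE 0.23). Against aviremic donors IFNG was 2.87-fold higher (1.52, SE 0.32), PDLIM1 2.86-fold (1.52, SE 0.23) and CD160 3.11-fold (1.64, SE 0.34), and LEF1 was 2.68-fold lower (-1.42, SE 0.27; n = 6 and 8). With the replicate block as a random effect IFNG lost its call against aviremic donors (adjusted p = 0.0805). In limma 188 genes passed against negative donors (119 rose and 69 fell) and 75 against aviremic donors (22 rose and 53 fell).

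Against negative donors the other large rises in TIGIT+ cells were DNAI3 (1.50, SE 0.26), the DNA sensor gene AIM2 (1.39, SE 0.31), the adhesion gene VCAM1 (1.37, SE 0.30), CD160 (1.26, SE 0.30), the calcineurin regulator gene RCAN2 (1.25, SE 0.24) and IGLV9-49 (1.17, SE 0.26). The other large falls were RASGRF2 (-1.48, SE 0.22), the mineralocorticoid receptor gene NR3C2 (-1.41, SE 0.26), TAMALIN (-1.39, SE 0.28), TXK (-1.28, SE 0.24), TANC2 (-1.21, SE 0.29) and MID2 (-1.16, SE 0.24). Without the donors that held a doubted array 9 of 25 named genes lost their call. Among them were AIM2 (log2 difference 1.33, adjusted p = 0.0613), VCAM1 (1.10, adjusted p = 0.0889), CD160 (1.11, adjusted p = 0.10) and TANC2 (-1.19, adjusted p = 0.0786). AIM2, RCAN2 and IGLV9-49 also rose against aviremic donors, by 1.44 (SE 0.34), 1.25 (SE 0.27) and 1.24 (SE 0.29), with CLIC3 (0.97, SE 0.23) and SLC1A4 (0.96, SE 0.20). All 5 lost their call with the 5th percentile covariate (adjusted p from 0.0542 for IGLV9-49 to 0.105 for CLIC3), at log2 differences from 0.89 for CLIC3 to 1.40 for AIM2. All but IGLV9-49 also lost it without the donors that held a doubted array (adjusted p from 0.0550 to 0.0983), at 0.85 for SLC1A4 to 1.41 for AIM2. The differences thus stayed of similar size. TXK (-1.56, SE 0.26), RASGRF2 (-1.49, SE 0.24), NR3C2 (-1.45, SE 0.29), RCAN3 (-1.28, SE 0.26), SERINC5 (-1.26, SE 0.22), VSIG1 (-1.22, SE 0.21) and MID2 (-1.22, SE 0.26) fell against aviremic donors.

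Naive and central memory genes fell in 8 of 19 cases in TIGIT+ cells of viremic against negative donors, and in 12 when adjusted over the list alone (adjusted p = 0.0326 with an estimated correlation). Against aviremic donors 8 fell, and 16 when adjusted over the list alone (adjusted p = 0.00695 with an estimated correlation). The 8 falls against negative donors became 4 without the donors that held a doubted array, and the 8 against aviremic donors became 4 with the 5th percentile covariate. The chromatin organiser gene SATB1 fell by 0.89 (SE 0.14) and BACH2 by 1.05 (SE 0.18) against negative donors, and IL7R, a cytokine receptor of long-lived T cells, by 0.78 (SE 0.15) against aviremic donors. Cell cycle genes rose in 3 of 17 cases against negative donors, KIF11 (1.04, SE 0.27), CCNA2 (0.97, SE 0.22) and PCNA (0.49, SE 0.11), and in 8 when adjusted over the list alone (adjusted p = 0.231 with an estimated correlation). Cytotoxic granule genes rose in 2 of 13 cases, NKG7 (0.54, SE 0.13) and CST7 (0.29, SE 0.08), and in 6 with 1 fall when adjusted over the list alone (adjusted p = 0.395 with an estimated correlation). Without the donors that held a doubted array the log2 differences were 0.96 for CCNA2, 0.89 for KIF11, 0.44 for PCNA, 0.45 for NKG7 and 0.24 for CST7. None of these 5 genes then kept its call (adjusted p from 0.0669 for CCNA2 to 0.120 for KIF11). NKG7 and CST7 also lost it with the block as a random effect (adjusted p = 0.297 and 0.507). KIF11 lost it, at log2 differences of 1.03 to 1.07, with median centring (adjusted p = 0.0575), quantile normalization (0.0520), no filter (0.0594), a trend with a robust prior (0.0537) and the covariate (0.0563). None of 20 interferon-stimulated genes passed over all genes tested, and 11 rose when adjusted over the list alone (median 0.62; adjusted p = 0.395 with an estimated correlation). OAS1 had a log2 difference of 1.13 (SE 0.36, adjusted p = 0.0993).

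CD4 and regulatory T cell markers were lower as a list in TIGIT+ cells of viremic donors, with a median of -0.34 against negative donors (adjusted p = 0.0326 with an estimated correlation). Against aviremic donors the median was -0.48 (adjusted p = 0.00456 with an estimated correlation), and 4 of 6 fell when adjusted over the list alone and 0 over all genes. Gamma-delta and MAIT cell markers had a median of -0.41 against negative donors, with 4 of 7 falling when adjusted over the list alone and 0 over all genes (adjusted p = 0.0497 with an estimated correlation). B cell, monocyte and platelet markers had no member past the threshold in either comparison. The counts rested on few donors. Against negative donors the count of 188 was 48 without viremic replicate 2 and 487 without negative replicate 11. Against aviremic donors the count of 75 was 27 without aviremic replicate 3 and 127 without negative replicate 2, whose arrays enter the shared spread.

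**Figure D3:**
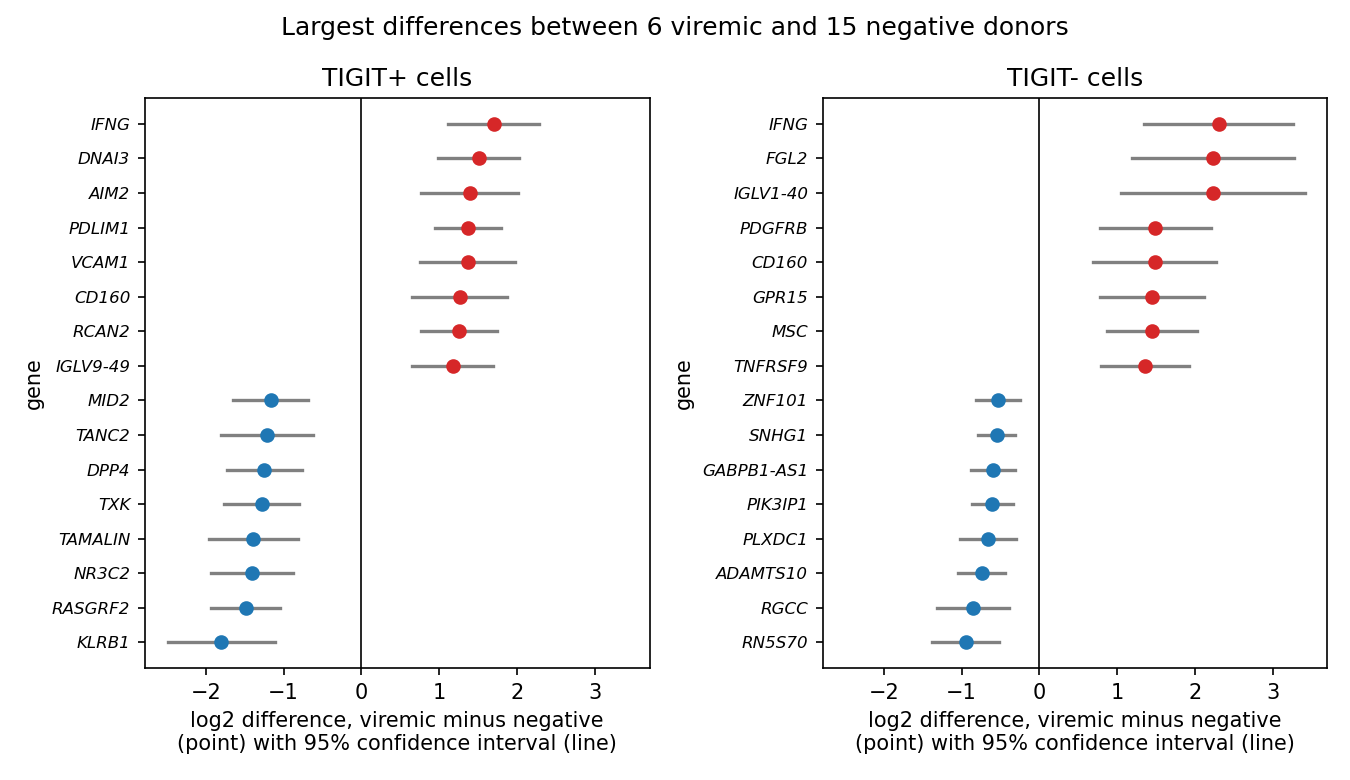
Log2 difference between 6 viremic and 15 negative donors (horizontal axis, points, with 95% confidence intervals as lines) of the genes with the largest rises and falls past the threshold (vertical axis) in TIGIT+ cells (left) and TIGIT- cells (right). IFNG leads the rises in both fractions, at 1.70 and 2.30.

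TIGIT- cells of viremic donors were compared with those of the other donors to ask whether cells sorted as lacking the receptor also differ with viremia. They had more transcripts of cell division genes and of IFNG, but most calls rested on few donors. Both doubted arrays were of TIGIT+ cells, so leaving out their donors removed 2 TIGIT- arrays that were not doubted. IFNG then lost its call against negative (log2 difference 2.17, adjusted p = 0.0627) and aviremic donors (2.51, adjusted p = 0.0543), as did 20 of 23 and 23 of 26 named genes in all. Against negative donors IFNG was 4.94-fold higher (2.30, SE 0.47), FGL2, a secreted fibrinogen-like protein, 4.70-fold (2.23, SE 0.51), the proliferation marker MKI67 2.38-fold (1.25, SE 0.24) and TNFRSF9 2.56-fold (1.35, SE 0.28; n = 6 and 15). Against aviremic donors IFNG was 5.74-fold higher (2.52, SE 0.53), CD160 4.13-fold (2.04, SE 0.43) and TOX 2.84-fold (1.51, SE 0.31; n = 6 and 8). In limma 214 genes passed against negative donors (183 rose and 31 fell) and 219 against aviremic donors (165 rose and 54 fell). TIGIT itself was not past the threshold, with log2 differences of 0.81 (SE 0.22, adjusted p = 0.0540) and 0.88 (SE 0.25, adjusted p = 0.0571).

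Cell cycle genes rose in 8 of 17 cases in TIGIT- cells of viremic donors against negative donors and in 8 against aviremic donors, and in 11 and 13 when adjusted over the list alone. The list passed camera with either correlation (adjusted p = 0.0389 and 0.0302 with an estimated correlation). Without the donors of the 2 doubted TIGIT+ arrays 3 and 1 of its genes rose. MKI67 then lost its call in both comparisons, at log2 differences of 1.11 (adjusted p = 0.0627) and 1.17 (adjusted p = 0.0702). RRM2, a subunit of ribonucleotide reductase, rose by 0.85 (SE 0.13) against negative and 0.96 (SE 0.14) against aviremic donors, KIF11 by 1.30 (SE 0.23) and 1.29 (SE 0.26), and NUSAP1 by 1.24 (SE 0.22) and 1.21 (SE 0.25). Activation markers rose in 2 of 15 cases against negative donors, TNFRSF9 and the death receptor gene FAS (0.89, SE 0.23), and in 9 when adjusted over the list alone (adjusted p = 0.214 with an estimated correlation). Against aviremic donors 4 rose, among them HLA-DMA (1.02, SE 0.24) and CD74 (0.69, SE 0.18), and 10 when adjusted over the list alone (adjusted p = 0.191 with an estimated correlation). Effector transcription factors rose in 2 of 17 cases in each comparison, IRF4 (1.06, SE 0.26) and BATF (0.72, SE 0.15) against negative donors (adjusted p = 0.262 with an estimated correlation) and TOX and BATF against aviremic donors (adjusted p = 0.191 with an estimated correlation). Without the donors of the 2 doubted TIGIT+ arrays no activation marker and no effector transcription factor passed in either comparison, with TNFRSF9 at 1.31, FAS at 0.81 and BATF at 0.66 against negative donors and CD74 at 0.70 against aviremic donors. With the covariate no activation marker passed against aviremic donors, with TNFRSF9 at 1.30, HLA-DMA at 0.90, CD74 at 0.66 and IL2RB at 0.63.

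Cytotoxic granule genes rose in 0 of 13 cases in TIGIT- cells against negative donors over all genes and in 10 when adjusted over the list alone (median 1.06; adjusted p = 0.264 with an estimated correlation). Against aviremic donors 1 rose, GZMM (0.58, SE 0.14), and 11 when adjusted over the list alone (median 1.14; adjusted p = 0.191 with an estimated correlation). PRF1, which encodes perforin, had a log2 difference of 1.12 (SE 0.31, adjusted p = 0.0540) against negative and 1.14 (SE 0.34, adjusted p = 0.0682) against aviremic donors. Interferon-stimulated genes rose in 0 of 20 cases, and in 15 against negative and 3 against aviremic donors when adjusted over the list alone (adjusted p = 0.271 and 0.323 with an estimated correlation). Inhibitory receptors other than TIGIT rose in 1 of 11 cases against negative donors, CD160 (1.48, SE 0.38), and in 2 against aviremic donors, CD160 and CD244 (1.14, SE 0.29; adjusted p = 0.161 and 0.191 for the list with an estimated correlation). None passed in either comparison with the covariate or without the donors of the 2 doubted TIGIT+ arrays. In these 2 settings CD160 stood at 1.35 and 1.40 against negative donors and at 1.69 and 2.08 against aviremic donors. CD244 stood at 1.14 and 1.11 against aviremic donors. No B cell, monocyte or platelet marker of the fixed lists passed in either comparison. The immunoglobulin gene IGLV1-40 rose by 2.23 (SE 0.58) against negative donors. It lost its call without the filter (adjusted p = 0.0564), with a trend and robust prior (0.0582), with the covariate (0.0547) and without the donors of the 2 doubted TIGIT+ arrays (0.142). Its log2 difference stayed between 2.23 and 2.27 in these settings.

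The other large rises in TIGIT- cells against negative donors were the growth factor receptor gene PDGFRB (1.49, SE 0.35), the gut-homing receptor gene GPR15 (1.45, SE 0.33) and the transcription factor gene MSC (1.44, SE 0.28). Against aviremic donors they were DTHD1 (1.79, SE 0.44), the phospholipase gene PLCG2 (1.62, SE 0.37), PDGFRB (1.61, SE 0.39) and PDLIM1 (1.52, SE 0.26). Falls were smaller. Against negative donors they were led by RN5S70 (-0.95, SE 0.21), RGCC (-0.86, SE 0.23), ADAMTS10 (-0.74, SE 0.15), PLXDC1 (-0.66, SE 0.18) and PIK3IP1, an inhibitor of phosphoinositide 3-kinase (-0.61, SE 0.13). Against aviremic donors they were led by ARRDC4 (-1.03, SE 0.27), RN5S70 (-1.03, SE 0.24), RASA4B (-0.85, SE 0.23), GABPB1-AS1 (-0.84, SE 0.16) and ADAMTS10 (-0.82, SE 0.17). These counts moved strongly with single donors. Against negative donors the count was 12 without viremic replicate 3 and 1290 without negative replicate 11. Against aviremic donors it was 15 without viremic replicate 3 and 645 without negative replicate 11. Without the 2 donors whose TIGIT+ array was doubted, and so without 2 TIGIT- arrays that were not, 13 and 8 genes passed.

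Aviremic donors were compared with negative donors to ask whether a difference remains without viremia. No gene passed in limma in TIGIT+ cells (812 at an unadjusted p under 0.05) or in TIGIT- cells (739 unadjusted). The smallest p values in TIGIT+ cells belonged to the collagen gene COL1A1 (-0.33, SE 0.08), RTN4IP1 (0.38, SE 0.10) and SNED1 (0.36, SE 0.09; adjusted p = 0.828 for each). In TIGIT- cells they belonged to GARS1-DT (0.47, SE 0.10, adjusted p = 0.671), the kinase gene MAPK13 (-0.24, SE 0.06) and WASHC4 (0.27, SE 0.07; adjusted p = 0.905 for each). Immediate early genes were lower as a list in TIGIT- cells of aviremic donors with the preset correlation (median -0.25, adjusted p = 4.38e-07), with FOSB at -0.92 (SE 0.34) and JUN at -0.44 (SE 0.18; adjusted p = 0.905 for each), and not otherwise (adjusted p = 0.529 with an estimated correlation). Gamma-delta and MAIT cell markers were lower in TIGIT+ cells with the preset correlation (median -0.23; adjusted p = 0.198 with an estimated correlation), with TRDC at -0.90 (SE 0.51, adjusted p = 0.831). Recovery was not simulated for this comparison. For viremic against negative donors, groups of 6 and 15, 98% of 2-fold but 22% of 1.25-fold differences were recovered in simulated data. Small differences may therefore have been missed.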

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

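The test of class II against B cell transcripts was chosen only after the result was seen; the other tests below were set before their results were seen.

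Transcripts of B cells, monocytes and platelets were higher in the TIGIT+ fraction, with IGHM at 8.39 against 6.19 and MS4A1 at 4.80 against 2.9. Of 9 measured genes of a further list of B-lineage markers 6 rose, against 22.2% of all genes, the largest being AFF3 (0.40, SE 0.06), while CR2 fell (-0.99, SE 0.09). Such rises are what B cells carried into the TIGIT+ fraction would give, and a sort for CD8+ T cells should remove them. Other values go against it: CD79A, abundant in B cells, stood at 6.68 against 6.92, SPIB had a log2 difference of 0.04 (SE 0.05) and CD37 of -0.06 (SE 0.04), and 2 of the 6 rises, PAX5 and FCRL1, lay in the lowest 10% of genes by level. The high levels of CD79A and CD37 in TIGIT- cells would hide a small share of B cells, so these values do not exclude it. A gain of class II transcripts from the same B cells was tested over the 29 donors: the class II genes, higher in 29 of 29 donors (7 of 7 measured rose), and the B cell markers that rose had a Pearson r of 0.139 (permutation p = 0.467; Spearman rho 0.113, permutation p = 0.555; r 0.225 within status and 0.0383 without the 2 farthest donors). The interval of r from -0.313 to 0.530 leaves that open, so class II expression by T cells and by carried B cells cannot be told apart. Other cells, such as the monocytes whose markers also rose, were not tested as a source. B cells in the sorted fraction may therefore contribute to the immunoglobulin signal, and expression of these genes by TIGIT+ T cells themselves was not tested.

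More genes were higher than lower in TIGIT- cells of viremic against negative donors (183 and 31). The 5th percentile of the TIGIT- arrays, a measure of background, was only 0.012 higher in viremic than in negative donors. With it as a covariate 121 of 183 rises stayed past the threshold, and their median changed from 0.54 to 0.53. For the comparison with negative donors this argues against a difference in that percentile as the whole cause. A covariate so similar in both groups could remove little, so background of another kind is not excluded. Against aviremic donors the count of genes fell more with the covariate, and 14 of 26 named genes lost their call. A part of that percentile in those calls is not excluded. A score of each TIGIT- array along the TIGIT+ against TIGIT- profile of the aviremic donors was 0.454 higher in viremic (0.45 ± 0.15, SD, n = 6) than in negative donors (SD 0.35, n = 15; exact permutation p = 0.00752 over 54264 splits, 95% interval 0.247 to 0.650), beside a difference between fractions of 0.85 within negative donors. Within viremic donors the difference between fractions was 0.69 ± 0.18 (SD, n = 6), so their TIGIT+ arrays also scored higher than those of negative donors. That rise was not tested, and TIGIT+ cells carried into the TIGIT- fraction would not cause it. TIGIT- cells of viremic donors may thus have moved towards the TIGIT+ profile, alone or together with TIGIT+ cells. TIGIT+ cells carried into the TIGIT- fraction, which the sort should remove, would raise the TIGIT- score too. Of the 183 rises 46 had a TIGIT- mean at or above the TIGIT+ mean in viremic donors (25.1%), between the 10% and 50% set as limits. TIGIT itself stood at 3.98 ± 0.34 (SD, n = 6) in TIGIT- cells of viremic and 3.17 ± 0.57 (SD, n = 15) in those of negative donors, a difference not past the threshold. Carried TIGIT+ cells would raise it, and a move towards the TIGIT+ profile may as well. A move of TIGIT- cells and carried TIGIT+ cells therefore cannot be told apart. The mix of cells within the TIGIT- fraction was not measured.

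NK cell transcripts were higher in the TIGIT+ fraction, with KLRF1 at 6.77 against 4.91 and TYROBP at 7.29 against 5.63. Of 9 measured genes of a further list of NK cell markers 5 rose, led by TTC38 (0.84, SE 0.11) and CLIC3 (0.78, SE 0.08), and CD7, which NK and T cells both express, fell (-0.52, SE 0.06); NK cells carried into the TIGIT+ fraction would give such rises, although a gate on T cells should remove them. FCER1G, abundant in NK cells, had a log2 difference of -0.39 (SE 0.18, adjusted p = 0.0839), which goes against it. Fewer alpha-beta T cells in the TIGIT+ fraction could not be read from the receptor complex, of which 2 of 6 genes fell (CD3E -0.23, SE 0.04, and CD8B -0.19, SE 0.05) and 2 rose (CD3D 0.16, SE 0.04, and CD247 0.17, SE 0.04). Expression of NK genes by TIGIT+ T cells is a candidate explanation that these tests leave open beside carried NK cells. Of 7 gamma-delta and MAIT cell markers 1 rose, TRDC, and 5 fell, and gamma-delta T cells were not tested as a source.

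The difference of the TIGIT effect between viremic and negative donors passed camera for 4 lists, each lower in viremic donors: effector transcription factors (adjusted p = 0.0445), effector cytokines and chemokines (adjusted p = 0.0445), homing receptors (adjusted p = 0.0445) and CD4 and regulatory T cell markers (adjusted p = 0.0451), all with an estimated correlation. With fry each of the 4 lost its call (adjusted p = 0.0622). A donor stood apart from its group, by the ratio of the gap to the range, in the paired difference of the oxidative phosphorylation genes in aviremic donors (ratio 0.536), in that of the platelet and erythroid markers in aviremic donors (0.546) and in the TIGIT level of TIGIT+ cells in viremic donors (0.735); these were 3 of 48 summary values, and chance gives about 1 in 20. Among the genes named for all donors, 6 of 115 paired differences had such a donor in the aviremic and 6 of 115 in the viremic group. Among levels of genes named in status comparisons there were 7 of 79 in aviremic and 4 of 79 in viremic TIGIT+ cells, and 9 of 91 in aviremic and 6 of 91 in viremic TIGIT- cells. Of 1327 probes with several symbols, not used in the comparisons, 691 passed between TIGIT+ and TIGIT- cells (286 rose and 405 fell), and of 8527 probes without a symbol 2472 did (689 rose and 1783 fell).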

How the results depend on the processing

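Leaving out the donors with a doubted array and the 5th percentile covariate were chosen after seeing the data. No named gene past the threshold changed its direction under any setting, and of 97 named genes called over all donors 1 lost its call, IFI6 without the block (adjusted p = 0.108). The counts over all donors and within negative donors stayed within 1.5 times under every setting, and without donors left out in turn they ranged from 6033 to 6408 and from 4174 to 4741. Without the replicate block, that is unpaired, 5276 genes passed over all donors, 2026 in aviremic and 564 in viremic donors, against 3163 and 1442 when paired; the spread between donors then enters the error. Leaving out donors gave 2383 to 3627 in aviremic and 831 (without viremic replicate 5) to 1729 in viremic donors. With an estimated correlation 1 of 15 lists kept its call over all donors, as the correlation within lists exceeded the preset.

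For the difference of the TIGIT effect between viremic and aviremic donors quantile normalization gave 1 gene (GRK5) and array weights gave 2 (GRK5 and TOX). Leaving out donors gave 0 to 1 across statuses and 0 to 1 for viremic against negative donors, the 1 (SPOCK2) without viremic replicate 1, and 0 for the other differences. These 3 genes fell under the naming rule through their small p. The cause was not tested.

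Status comparisons depended most on the setting. In TIGIT- cells the count for viremic against aviremic donors, 219, was 139 with median centring, 110 without the filter, 423 with only probes above the 75th percentile, 1291 with array weights, 659 with the replicate block as a random effect, 8 without the donors with a doubted array and 69 with the 5th percentile covariate. For viremic against negative donors, 214, it was 429 above the 75th percentile, 1548 with array weights, 603 with the block as a random effect and 13 without the doubted donors. Both doubted arrays were of TIGIT+ cells, so in TIGIT- cells that setting removed 2 arrays that were not doubted. In TIGIT+ cells the count for viremic against negative donors, 188, was 398 with the block as a random effect and 87 without the doubted donors, and that for viremic against aviremic donors, 75, was 226 with array weights and 45 with the covariate. Filters change the number of genes tested; for the other settings the cause was not tested.

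Single donors moved these counts by over 1.5 times. In TIGIT+ cells viremic against negative donors gave 48 without viremic replicate 2, 65 without viremic 6, 97 without viremic 4, 301 without viremic 1 and 487 without negative 11. Viremic against aviremic donors gave 27 without aviremic 3, 30 without viremic 2, 41 without viremic 4, 42 without viremic 6, 49 without aviremic 6, 120 without viremic 1 and 127 without negative 2. In TIGIT- cells viremic against negative donors gave 12 without viremic 3, 39 without viremic 6, 43 without viremic 4, 98 to 123 without negative 1, 2, 3, 4, 5, 8, 12, 13 or 14, 450 without negative 9, 770 without negative 15 and 1290 without negative 11. Viremic against aviremic donors gave 15 without viremic 3, 17 without viremic 6, 40 without aviremic 7, 44 without aviremic 5, 49 without viremic 4, 56 without aviremic 1, 75 without aviremic 2, 81 without aviremic 4, 84 without viremic 1, 124 without negative 7, 142 without negative 5, 398 without aviremic 6, 481 without negative 15, 485 without viremic 5 and 645 without negative 11. Aviremic against negative donors gave 0 in both fractions in all omissions. Signal near background limits genes below the filter, which were not tested.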

Other observations

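All tests in this part were set before their results were seen. Some differences with viremia did not hang on any single donor. In TIGIT+ cells of viremic against negative donors 25 named genes had passed and 14 of them lost their call in at least 1 omission of a donor; the others, which kept it in every omission, were the rises of IFNG (log2 difference 1.55 to 1.84), PDLIM1 (1.25 to 1.61), DNAI3 and RCAN2 and the falls of KLRB1 (-2.16 to -1.63), BACH2, SATB1 (-1.0 to -0.82), DPP4, NR3C2, RASGRF2 and TXK. In TIGIT- cells 21 of 23 lost their call in at least 1 omission, and KIF11 (1.15 to 1.54) and RRM2 (0.71 to 0.96), both of cell division, kept it. Against aviremic donors RRM2, PDLIM1 and GABPB1-AS1 kept their call in every omission in TIGIT- cells, where 23 of 26 did not, and PDLIM1, LEF1, SATB1, IL7R, SERINC5, TXK, RASGRF2 and VSIG1 in TIGIT+ cells, where 11 of 19 did not.

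Other splits of the same samples were counted, the real split included. For TIGIT+ against TIGIT- cells fractions were swapped within donors. Chance is unlikely for 6281 genes over all donors (1 of 100 splits as large, highest other 2838) and for 4724 genes in negative donors (1 of 100, highest other 3837, with 1 donor swapped). The same holds for 3163 in aviremic donors (1 of 100, highest other 1635, with 1 donor swapped) and for 1442 in viremic donors (1 of 32, highest other 211). Since the real split is counted, 1 of 100 or 1 of 32 is the smallest share that could be found. Chance is therefore not excluded, here or for donor status below. For 15 lists at the preset correlation 2 of 100 splits were as large (highest other 15, median 4), so chance is unlikely but not excluded. Only 1 of the 15 lists kept its call with an estimated correlation, which the splits did not test. For donor status chance is unlikely for viremic against negative donors in TIGIT+ cells (188 genes, 1 of 100, highest other 9). The same holds for viremic against aviremic donors in TIGIT+ cells (75 genes, 1 of 100, highest other 2) and in TIGIT- cells (219 genes, 1 of 100, highest other 1). These counts still moved strongly with single donors. For viremic against negative donors in TIGIT- cells (214 genes) 2 of 100 splits were as large. The highest other split there gave 552 genes, more than the real split, so chance is unlikely but not excluded. Where no gene had passed, all 100 of 100 splits reach 0 genes by construction, so the count of splits says nothing about chance. The highest other was 7 for the TIGIT effect across statuses, 337 for viremic against negative, 1 for aviremic against negative and 1 for viremic against aviremic donors, and 2 in TIGIT+ and 423 in TIGIT- cells for aviremic against negative donors. The source of the splits with 337, 423 and 552 genes was not tested. A structure of the samples and correlation between genes are both candidates.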
